A study of Caenorhabditis elegans with 8 samples.

How the data were processed

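Total RNA from whole animals of 4 C. elegans strains under 2 RNAi treatments was hybridised to 8 Affymetrix C. elegans Gene 1.0 ST arrays, a single-colour array with probes along each transcript. Per the series' design text, the authors scanned and processed the arrays with Affymetrix GeneChip Command Console 2.0 and imported them into GeneSpring GX 11.0.2, and per the submitters' processing notes RMA was used. RMA subtracts background, equalises arrays by quantiles and summarises probes per feature; its version, the level of summarisation and any added offset are not given in the sources used here. The deposited table holds 1 intensity per feature and array on a linear scale, normalized by the authors. Its values run from 18.01 to 12880, none is missing, and the lowest values of every array lie near 18, so a floor or offset compresses differences of dim features and a fold change of a dim feature is understated. Array medians lie between 21.1 and 21.6, and 8693 of 27792 features have a mean intensity above 32, which limits what can be seen for the rest.

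Log2 of the deposited intensity was taken with nothing added and no feature filtered. Features were named through the platform annotation and gene identifiers of the RefSeq table of assembly WBcel235, used for names, biotypes and annotated lengths: 25546 features had exactly 1 symbol, 646 several and 1600 none, and features with several symbols were not named. The 25546 features covered 25478 genes, and 25495 of their identifiers were found in the RefSeq table. A gene with several features is given by the feature with the highest mean level. No coordinates are given, because the build behind the array is not given in the sources used here. Across 66 clusters, 253 features with a mean log2 above 5 had all 8 log2 values within 0.05 of a neighbour's, and are called near-identical.

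Groups follow the strain and RNAi labels, with 1 array in each of 8 groups. The control and ash-2-labelled arrays of a strain form a pair because they share the strain. As a check, over features with a mean log2 above 5, deviations from the treatment means correlated at 0.684 within N2, 0.574 within VP303, 0.839 within NR350 and 0.525 within TU3401, and each control array correlated best with the other array of its own strain. The first comparison fitted the treatment with strain as a block (3 residual degrees of freedom). The second fitted the mean response of N2 and VP303 against that of NR350 and TU3401 (2 residual degrees of freedom). Strains were compared with N2 in the first model. All used limma 3.58.1 (lmFit and eBayes with a trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Differences within a strain have no test and were counted at 2-fold.

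A total of 28 gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one, with fry beside them, for lists of at least 5 measured members. Of 451 genes named singly in the lists, 18 were not matched and 2 were matched through a synonym. Within a strain, list medians were compared with 10000 random lists matched in 20 bins of mean level. The tests, the lists, the alternatives not marked otherwise and the rule for named genes were fixed before the data were examined. The rule took the RNAi target and strain markers, the 12 highest and 12 lowest genes with 1 symbol that moved the same way in all 4 strains, 8 per direction for the class contrast where both strains of a class lie beyond both of the other, the 5 highest and 5 lowest per strain and per strain difference, up to 5 genes changed in N2 and VP303 and not in the others, the extreme members of each list and 12 reporter genes. Members of families with near-identical copies are given as uncertain.

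On simulated data with the residual spread of these arrays, 200 of 27792 features changed by 2-fold or 4-fold in each of 5 runs. The changed features were drawn from those with a mean log2 above 5, so recovery among dimmer features was not measured. Each change had 1 size in every strain in which it was made, and features were drawn independently. Recovery of responses whose size varies more between strains was thus not measured. The shared contrast recovered 80.8% and 98%, the class contrast 1.6% and 45.4%, and a strain against N2 53.2% and 94.6%; 3.04%, 1.67% and 4.15% of calls were false. In 1 simulated run where 1 list was shifted by 0.5, camera with the preset correlation called that list and 0 of the others. Genes were drawn independently there, so the run does not show how camera behaves on lists whose genes move together. The alternatives fixed beforehand were quantile normalization, centring on medians, dropping dim features, eBayes without a trend or with a robust prior, features with 1 symbol, a threshold of 0.10, no strain block, leaving out each strain, and a 1.5-fold threshold. Alternatives chosen after seeing the data were log2 of the intensity minus 16, near-identical features counted once, protein-coding genes only, and the lists tested between strains. Neither quantile normalization nor median centring moved the median difference of all features within a strain by more than 0.0125. Intervals of medians are 95% bootstrap intervals over genes from 2000 draws. Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.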

Results

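Gene expression was measured in whole Caenorhabditis elegans with 8 Affymetrix C. elegans Gene 1.0 ST arrays, 1 array for each combination of 4 strains and 2 RNAi treatments. Per the labels, RNAi acts in the whole body of N2, the wild type, in the intestine of VP303, in the muscle of NR350 and in the neurons of TU3401. Feeding on control bacteria or on bacteria targeting ash-2 lasted 3 days, starting at the egg and ending in young adults, at 20 °C. The gene ash-2 encodes a subunit of the complex that methylates lysine 4 of histone H3. The series title places the work on epigenetic information passed from the intestine to the germ line, and the arrays address which genes respond when ash-2 RNAi acts in different tissues. Each array held 27792 features, with a median intensity between 21.1 and 21.6, and 31.3% of the features had a mean intensity above 32. With 1 array per group, the 4 strains were the only repeats, no label names separate cultures, and the p-values below rest on how far the difference between the treatments varied from strain to strain. The number of arrays limits the precision.

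The signal of ash-2, the gene targeted by the RNAi, was higher in the array labelled ash-2 than in the control array of every strain, against the direction of a knockdown. The log2 difference was 0.29 in N2, 0.65 in VP303, 0.89 in NR350 and 0.69 in TU3401, with a mean of 0.63 ± 0.25 (SD, n = 4 strains, limma adjusted p = 0.302). Because the target gene went against the labels, the treated arrays are called the arrays labelled ash-2 throughout, and every direction of response rests on those labels. Genes commonly used as transgenes or markers separated the strains. The cuticle collagen rol-6, a common transformation marker, had a mean log2 level of 12.16 in VP303 and 4.64 in N2, where its intensity lay under 32, so the difference of 7.52 (SE 0.15) depends on the floor of the scale; rde-1, the Argonaute needed for RNAi, was 5.48-fold higher (2.45, SE 0.13). The marker gene sur-5 was 14.3-fold higher in NR350 than in N2 (3.84, SE 0.13), where rde-1 did not differ by the limma test (-0.21, SE 0.13, adjusted p = 0.47). The dsRNA channel gene sid-1 was 3.44-fold higher in TU3401 than in N2 (1.78, SE 0.15). The adjusted p of limma was 8.24e-10 for rol-6 and 8.71e-06 for rde-1 in VP303, 7.31e-08 for sur-5 in NR350 and 3.11e-04 for sid-1 in TU3401.

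**Figure D1:**
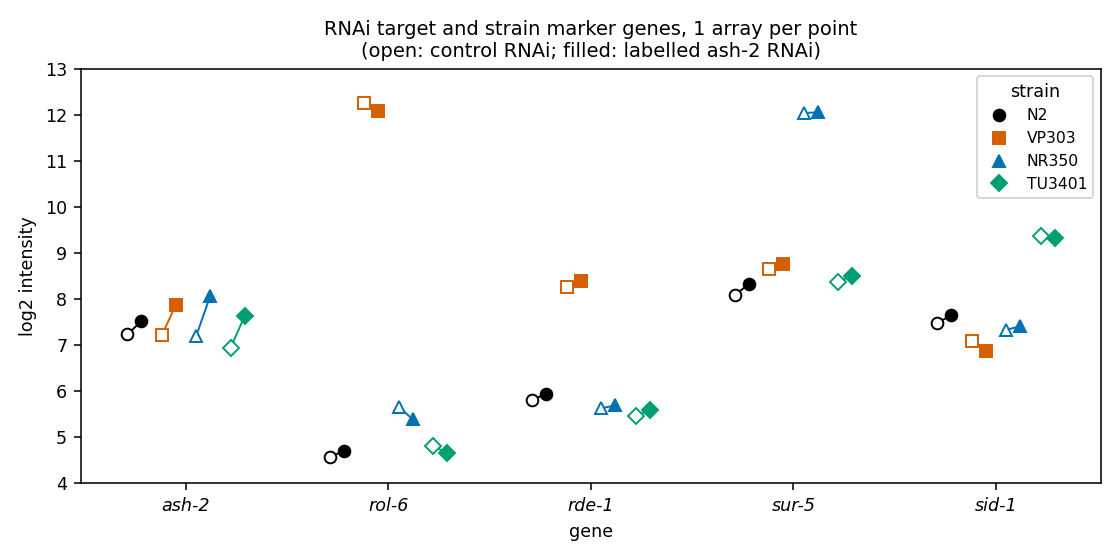
Log2 intensity (vertical axis) of the RNAi target ash-2 and 4 strain marker genes (horizontal axis) on each of the 8 arrays; open symbols are control arrays, filled symbols arrays labelled ash-2, and lines join the arrays of 1 strain. The filled ash-2 symbol lies above the open one in all 4 strains, and rol-6 and rde-1 stand out in VP303, sur-5 in NR350 and sid-1 in TU3401.

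The first comparison asked which genes respond to ash-2 RNAi in the same way in the 4 strains. Among genes with 1 symbol that moved the same way in all 4 strains, the largest mean difference was that of asp-14, an aspartyl protease gene, which was higher in the array labelled ash-2 by 1.06 in N2, 1.67 in VP303, 3.05 in NR350 and 1.77 in TU3401 on the log2 scale (mean 1.89 ± 0.83 SD, n = 4, 3.70-fold). C32H11.4 had a mean of 1.08 ± 0.72, from 0.34 in N2 to 2.06 in NR350. The strongest shared differences in the other direction were those of Y54G2A.10 (-1.72 ± 1.27, from -3.22 in N2 to -0.28 in TU3401), the noncoding F26H11.9 (-0.999 ± 0.621) and aps-3, a subunit of the AP-3 sorting adaptor (-0.83 ± 0.42). No feature passed the limma test at an adjusted p under 0.05, and the smallest adjusted p was 0.107, while 1041 features were higher and 1180 lower at an unadjusted p under 0.05.

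Among the other genes with the highest shared means, none of which passed the limma test, were iffb-1, a translation initiation factor (0.57 ± 0.28), rpoa-2, a subunit of RNA polymerase I (0.53 ± 0.39), glp-4, a valyl tRNA synthetase (0.52 ± 0.37), and ATP6, a mitochondrially encoded subunit of ATP synthase (0.57 ± 0.36). The remaining genes named on that side by the rule were C27C12.3 (0.64 ± 0.48), T27E4.7 (0.62 ± 0.26), drd-50 (0.56 ± 0.34), C50B6.3 (0.54 ± 0.30) and the RNA-binding gene rbm-3.2 (0.51 ± 0.34), beside ash-2 itself. On the lower side, the noncoding F52H3.10 differed by similar amounts in every strain (-0.89, -0.64, -0.90 and -0.60), with a mean of -0.76 ± 0.16. The noncoding Y47H9A.4 (-0.62 ± 0.20), C18A3.14 (-0.64 ± 0.30), Y73B3A.23 (-0.65 ± 0.46) and T27E4.15 (-0.65 ± 0.50) had smaller means. The protein-coding Y27F2A.8 (-0.82 ± 0.57), T15B7.1 (-0.73 ± 0.40), Y60A3A.16 (-0.71 ± 0.39) and phat-8 (-0.63 ± 0.59) completed the lower group. When only the 25546 features with exactly 1 gene symbol were tested, asp-14 rose and F52H3.10 fell at a limma adjusted p of 0.0239 each. Without the TU3401 arrays, 1 feature, asp-14, was higher and 24 were lower at an adjusted p under 0.05 in limma. In data simulated with the residual spread of these arrays, limma recovered 80.8% of 2-fold and 98% of 4-fold changes shared by the 4 strains. Those changes were made only in features with a mean log2 above 5, had 1 size in all 4 strains, and numbered 200 per run. Features were drawn independently. In the real data, asp-14 (3.70-fold, SD 0.83) and Y54G2A.10 (-1.72, SD 1.27) varied in size between strains and did not pass over all features. The recovered shares thus do not exclude large shared changes whose size varies between strains. With each array centred on its median, the split at an unadjusted p under 0.05 in limma was 1344 higher and 849 lower. Without a variance trend it was 1285 and 904.

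**Figure D2:**
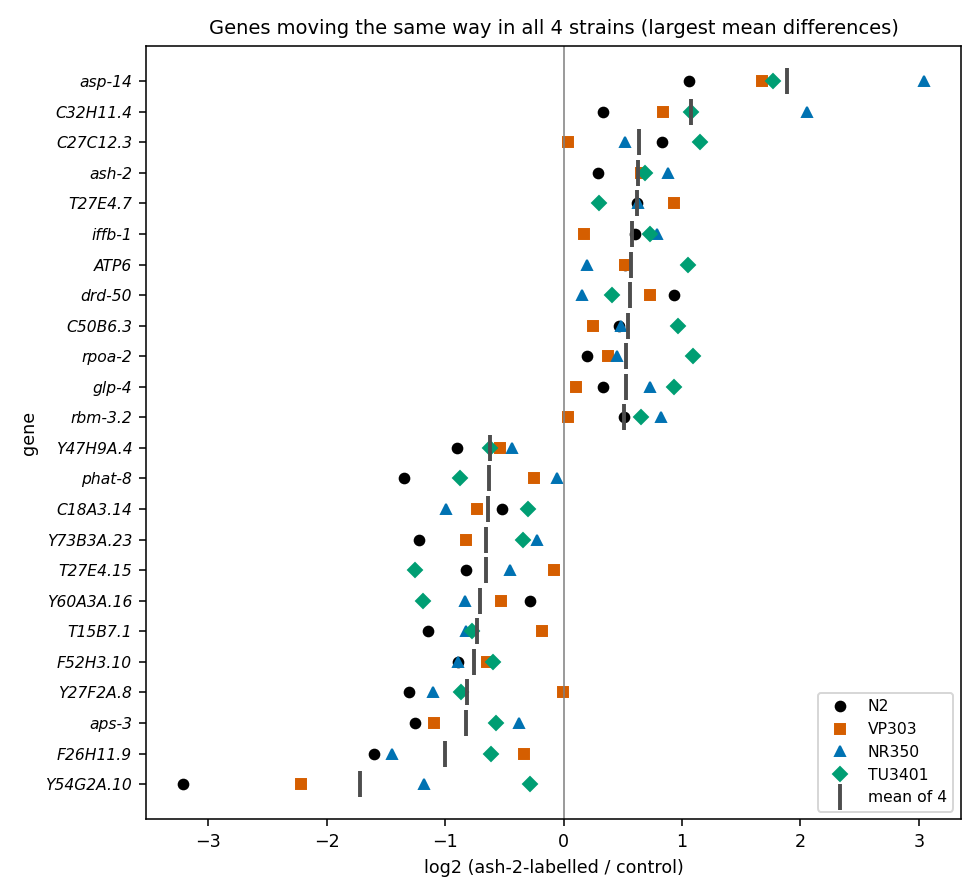
Log2 ratio of the array labelled ash-2 to the control array (horizontal axis) in each of the 4 strains (symbols) for the 24 genes (vertical axis) with the largest mean differences among genes that moved the same way in all 4 strains; vertical ticks are means of the 4 strains. The asp-14 mean is 1.89 and the Y54G2A.10 mean is -1.72.

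Of 12 reporter genes of stress and metabolism, 8 had mean log2 differences close to 0. The superoxide dismutase gene sod-3 had a mean log2 difference of -0.002 ± 0.041 (SD, n = 4), the small heat shock gene hsp-16.2 of 0.025 ± 0.033 and the metallothionein gene mtl-1 of 0.06 ± 0.05, all with mean intensities under 32. The glutathione genes gst-4 (-0.03 ± 0.35) and gcs-1 (0.04 ± 0.18) showed no common direction in the 4 strains. The fatty acid desaturase genes fat-5 (-0.01 ± 0.09), fat-6 (-0.06 ± 0.06) and fat-7 (0.04 ± 0.20) had means close to 0. The endoplasmic reticulum chaperone hsp-4 (0.18 ± 0.18), the mitochondrial chaperone hsp-6 (0.29 ± 0.10), the yolk protein gene vit-2 (0.30 ± 0.15) and the immune gene sysm-1, also called T24B8.5 (0.41 ± 0.41), had higher means. The hsp-6 and vit-2 differences were positive in all 4 strains, while sysm-1 differed by 0.79 in N2 and 0.71 in VP303 but by -0.02 in NR350 and 0.13 in TU3401. The log2 level of sysm-1 was 4.75 and 4.74 on the NR350 arrays and 4.94 on the VP303 control array. These intensities lay under 32, so the floor limits the sysm-1 differences in NR350 and VP303. On the TU3401 arrays the level was 7.40 and 7.53. None of these 12 genes passed the limma test over all features, the smallest adjusted p being 0.377, for vit-2.

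The gene lists were used to ask which groups of genes shared a direction across strains. The yolk protein genes stood highest: all 5 measured vitellogenins had positive means, from 0.15 ± 0.17 for vit-5 to 0.40 ± 0.29 for vit-4, and the list median was 0.40 in N2, 0.19 in VP303, 0.16 in NR350 and 0.29 in TU3401. None of the 5 passed over all genes, and all 5 passed adjusted over the list alone; the close copies within this family make single members uncertain. Among 13 genes of the mitochondrial unfolded protein response, the median difference was 0.10, and ubl-5 (0.44 ± 0.15) and hsp-6 (0.29 ± 0.10) passed adjusted over the list alone, against 0 over all genes. Respiratory chain subunits had a median of 0.09, with sdha-1 (0.30 ± 0.14) and atp-2 (0.25 ± 0.13) highest and nuo-6 (-0.14 ± 0.16) lowest. Cytosolic ribosomal proteins had a median of 0.08, with 0.12 in N2 and 0.15 in NR350 but 0.01 in VP303 and -0.01 in TU3401. Neither list had a member that passed adjusted over the list alone or over all genes.

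Several tissue and stress lists also had medians of the mean difference above 0. Muscle markers had a median of 0.22 in N2, 0.11 in VP303, 0.08 in NR350 and -0.03 in TU3401, and the myosin gene unc-54 (0.47 ± 0.53) and the paramyosin gene unc-15 (0.38 ± 0.28) were highest. Of 28 innate immunity effectors, 6 passed adjusted over the list alone and 0 over all genes. Of these 6, dod-24 (0.68 ± 0.61), lys-8, a lysozyme gene (0.50 ± 0.21), K08D8.5 (0.47 ± 0.24) and irg-5 (0.30 ± 0.18) were higher, while the lysozyme gene lys-4 (-0.35 ± 0.22) and the lectin gene clec-67 (-0.34 ± 0.21) were lower. Germ line genes had a median of 0.09, with csr-1 (0.26 ± 0.20) highest and htp-1 (-0.39 ± 0.30) lowest. The medians were 0.05 for the endoplasmic reticulum unfolded protein response, with pek-1 highest (0.27 ± 0.14), 0.09 for moulting genes, 0.03 for the RNAi machinery and 0.02 for SKN-1 and glutathione genes, with skn-1 highest (0.32 ± 0.19). Single strains went the other way: the median was -0.02 in VP303 and -0.04 in NR350 for the RNAi machinery, -0.03 in NR350 for moulting genes and -0.04 in N2 for SKN-1 genes. Those 11 lists had camera adjusted p under 0.05 with the preset correlation of 0.01, from 5.38e-07 for ribosomal proteins to 0.0458 for SKN-1 genes, all in the higher direction and 0 lower. With an estimated correlation none held: the adjusted p was 0.418 for all 11, and fry gave an adjusted p of at least 0.352. With the preset correlation, 5 lists passed under quantile normalization and 7 without the N2 arrays.

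The other 17 lists did not pass. Cuticle collagens (median 0.01), heat shock genes (0.07) and the remaining H3K4 methylation machinery (0.06) came closest, with camera adjusted p of 0.0526, 0.068 and 0.068. In the H3K4 list, the demethylase rbr-2 (0.36 ± 0.29) and the methyltransferase set-2 (0.23 ± 0.16) were highest and set-17 (-0.27 ± 0.07) lowest. Intestine markers (0.03), lipid metabolism (0.04), epidermal antimicrobial peptides (0.01), histones (-0.06), oocyte and eggshell genes (0.04), DAF-16 targets (0.02) and DNA replication genes (0.03) had adjusted p between 0.123 and 0.292. Neuron markers (0.02), sperm genes (0.01), fatty acid desaturases and elongases (-0.02), cytochromes P450 (-0.002), insulin-like peptides (-0.006), the intracellular pathogen response (-0.007) and UDP-glucuronosyltransferases (0.001) lay between 0.521 and 0.807. For desaturases and elongases the mean (0.006) and the median differ in sign, and the medians of cytochromes P450, insulin-like peptides and the pathogen response change sign under median centring. Single members of these lists passed adjusted over the list alone, with 0 over all genes: nlp-34, an antimicrobial peptide gene (0.39 ± 0.10), the chaperone hsp-1 (0.28 ± 0.17) and acdh-1, an acyl-CoA dehydrogenase gene (-0.52 ± 0.39).

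**Figure D3:**
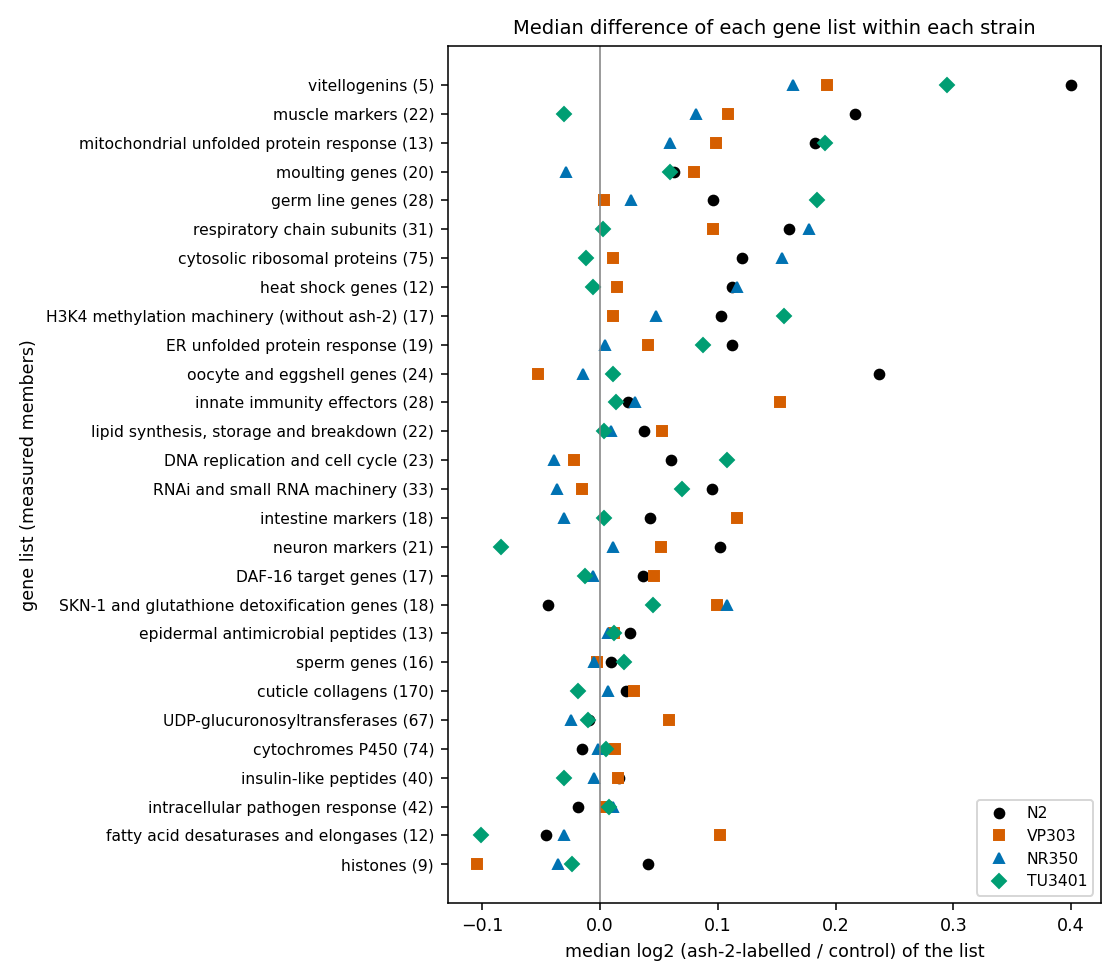
Median log2 ratio of the array labelled ash-2 to the control array (horizontal axis) over the measured members of each of 28 gene lists (vertical axis, number of members in brackets), 1 symbol per strain. Vitellogenins lie highest, with medians from 0.16 in NR350 to 0.40 in N2, and most other lists lie within 0.2 of 0.

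The second comparison set N2 and VP303, the strains in which the labels place the RNAi in the intestine, against NR350 and TU3401. The largest class differences were those of features lower in the arrays labelled ash-2 of N2 and VP303. On the N2 and VP303 control arrays several of them lay far higher than on the other control arrays: log2 levels were 11.33 and 10.82 for M163.12 against 8.56 in NR350 and 8.68 in TU3401, and 7.40 and 6.53 for F08G2.13 against 5.29 and 4.80, which for F08G2.13, as for pix-1 and T19B4.9, left little room for lower values there. Y54G2A.10 averaged -2.72 in N2 and VP303 and -0.73 in NR350 and TU3401. The guanine nucleotide exchange factor pix-1 averaged -1.51 and 0.26, and the noncoding T19B4.9 (-1.91 and 0.00), F08G2.13 (-1.66 and -0.11), F23F12.15 (-1.21 and 0.29), M163.15 (-1.93 and -0.44), M163.12 (-1.80 and -0.41) and C04E7.7 (-0.77 and 0.96) followed. C04E7.7 lay under or near an intensity of 32 on the NR350 arrays and the TU3401 control array, and its class difference rests largely on the TU3401 array labelled ash-2 (1.72 in TU3401, 0.20 in NR350). F23F12.15 is measured by several near-identical features and is uncertain. In the other direction, the insulin-like genes daf-28 (0.28 and -0.88) and ins-30 (0.42 and -0.67), the collagen gene col-94 (0.54 and -0.52), Y39B6A.1 (0.73 and -0.57), wip-1 (0.37 and -0.78), ZK669.2 (0.84 and -0.31), nssp-64 (0.30 and -0.76) and epic-2 (0.60 and -0.41) had the largest differences. No feature passed limma at an adjusted p under 0.05 (smallest 0.0821), while 827 were higher and 767 lower in N2 and VP303 at an unadjusted p under 0.05. With only features of exactly 1 symbol, pix-1, F08G2.13 and W01D2.7, the last chosen after its value was seen (class difference -0.93), were lower at a limma adjusted p of 0.0424. Leaving out 1 strain gave 16 higher and 35 lower features without N2, 13 and 42 without VP303, 20 and 32 without NR350, and 6 and 0 without TU3401, each fit then having a class of 1 strain that is assumed to vary like the others. In simulated data this contrast recovered 1.6% of 2-fold and 45.4% of 4-fold changes made in features with a mean log2 above 5.

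Within single strains, where 1 array stood against 1 array and no test was possible, features at least 2-fold lower outnumbered those higher in all 4 strains, but not among protein-coding genes in N2 and VP303. In N2, 12 features were at least 2-fold higher and 86 lower in the array labelled ash-2; in VP303 the numbers were 12 and 89, in NR350 11 and 29, and in TU3401 15 and 23. Of the lower features, 58 of the 86 in N2 and 72 of the 89 in VP303 had no gene symbol, so that their kind is unknown, and 12 and 11 were other than protein-coding with 1 symbol. Protein-coding genes with 1 symbol gave 10 higher and 10 lower in N2, and 8 higher and 3 lower in VP303. The largest N2 differences were Y54G2A.10 (-3.22), T19B4.9 (-2.50), M163.15 (-2.02), F08G2.13 (-1.85 in log2) and M163.12 (-1.82) on the lower side. On the higher side they were the mitochondrially encoded ND4L (1.41) and ND6 (1.26), epic-2 (1.29), the muscle myosin unc-54 (1.24) and F45D3.4 (1.21). In VP303, asp-14 (1.67), ZK669.2 (1.24), cyp-25A2 (1.18), F58B4.5 (1.17) and F01F1.2 (1.11) were highest, and Y54G2A.10 (-2.22), M163.15 (-1.85), M163.12 (-1.78), Y54G2A.70 (-1.53) and F08G2.13 (-1.47) lowest. In NR350, asp-14 (3.05), C32H11.4 (2.06), F55G11.2 (1.28), the immune gene dod-24 (1.28) and E03H4.8 (1.13) were highest, and F33E2.5 (-2.09), Y54G2A.70 (-1.50), F26H11.9 (-1.45), the small nuclear RNA F56A12.5 (-1.39) and F01D5.14 (-1.23) lowest. In TU3401, asp-14 (1.77), C04E7.7 (1.72), Y105E8A.36 (1.17), K03F8.3 (1.16) and C27C12.3 (1.15) were highest, and daf-28 (-1.33), the troponin C gene tnc-2 (-1.32), M04D5.4 (-1.29), T27E4.15 (-1.25) and scl-3 (-1.21) lowest. With near-identical features counted once, an alternative chosen after the data were seen, the lower counts were 39 in N2 and 29 in VP303. Under quantile normalization the TU3401 counts were 11 higher and 28 lower.

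N2 and VP303 shared more features at least 2-fold lower than any other pair of strains, of which 3 were protein-coding genes with 1 symbol. A set of 62 features was at least 2-fold lower in both, or 19 with near-identical features counted once, where 0.275 and 0.041 would overlap between independent lists, and 1, asp-14, was higher in both. The other 5 pairs shared at most 5 features in either direction. Of the 63 features changed in both, 41 differed by less than 1.5-fold in NR350 and TU3401, all of them lower in N2 and VP303; 36 of the 41 had no symbol and 4 had exactly 1. Those 4 were F08G2.13, T19B4.9, pix-1 and aps-3. The median log2 level of the 41 was 7.97 on the N2 control array and 8.22 on that of VP303, against 5.45 in NR350 and 6.10 in TU3401, and 6.93 and 6.39 on the N2 and VP303 arrays labelled ash-2. The 41 were 12 with near-identical features counted once, and 2 were protein-coding. Among protein-coding genes alone, N2 and VP303 shared 3 lower features and 1 higher, the same numbers as N2 and NR350. Across all features, which are not independent replicates, the log2 differences of N2 and VP303 had a Pearson correlation of 0.283 and a Spearman correlation of 0.0958. The other pairs had Pearson correlations of 0.257 (N2 and NR350), 0.189 (N2 and TU3401), 0.237 (NR350 and TU3401), 0.118 (VP303 and NR350) and 0.0625 (VP303 and TU3401). By Spearman correlation N2 and VP303 lay below N2 and NR350 (0.134), N2 and TU3401 (0.131) and NR350 and TU3401 (0.125). Among protein-coding genes alone, the Pearson correlation of N2 and VP303 was 0.0902, below N2 and NR350 (0.239), N2 and TU3401 (0.224) and NR350 and TU3401 (0.26). The strains share no array, so no common control enters these values.

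**Figure D4:**
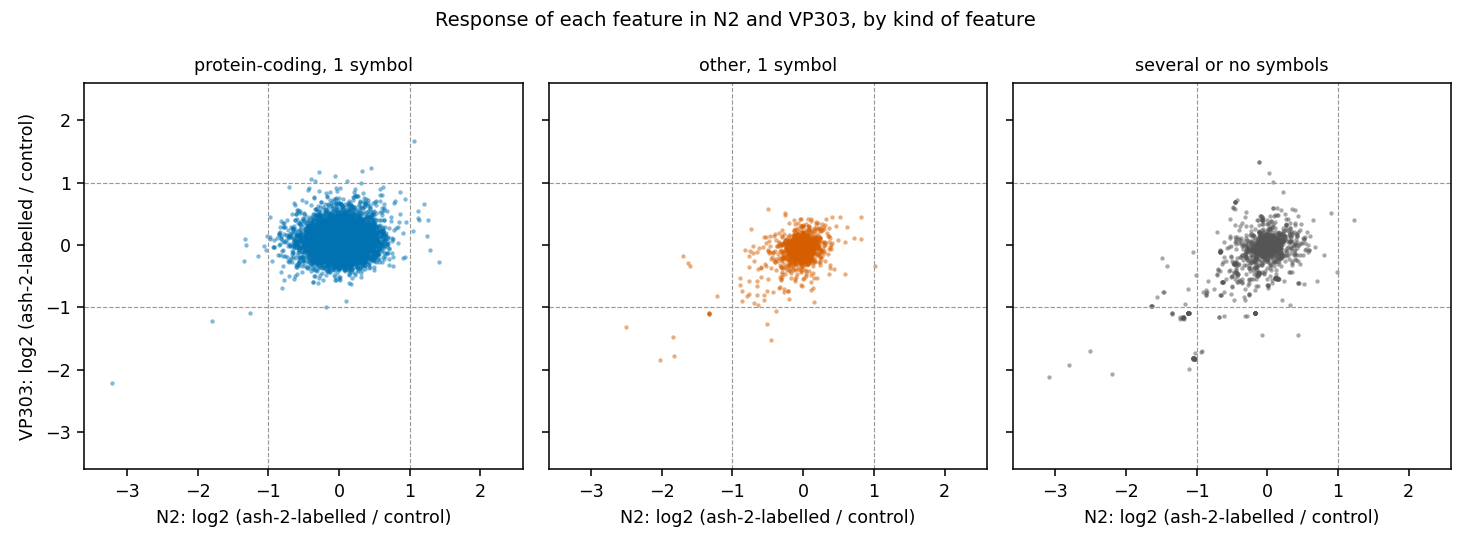
Log2 ratio of the array labelled ash-2 to the control array in N2 (horizontal axis) and VP303 (vertical axis), 1 point per feature, in panels for protein-coding genes with 1 symbol, other features with 1 symbol, and features with several or no symbols; dashed lines mark 2-fold. The 62 features lower in both strains lie mostly in the 2 panels on the right, and 3 of them are protein-coding genes.

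Within a strain, list medians were set against 10000 random lists of matched size and level. Of 112 medians, 20 lay above and 3 below the middle 95% of the random medians, where 2.8 on each side would lie by construction. Above that range in N2 were the vitellogenins, muscle markers, oocyte and eggshell genes (median 0.24), respiratory chain subunits, the mitochondrial unfolded protein response, collagens and neuron markers (0.10). In VP303, above that range were innate immunity effectors (0.15), respiratory chain subunits (0.10), UDP-glucuronosyltransferases (0.06), SKN-1 genes (0.10), collagens (0.03) and cytochromes P450 (0.01), with histones below (-0.10). In NR350, ribosomal proteins (0.15), respiratory chain subunits (0.18), heat shock genes (0.12) and SKN-1 genes (0.11) lay above and UDP-glucuronosyltransferases (-0.02) below. In TU3401, germ line genes (0.18), vitellogenins (0.29) and the mitochondrial unfolded protein response (0.19) lay above and neuron markers (-0.08) below. Genes of a list move together, so these percentiles describe the arrays and are not tests.

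More features passed the test between strains than between treatments. In these tests the 2 arrays of a strain, 1 per treatment, served as its repeats, and no label names separate cultures. Spread between cultures of a strain is thus not measured by the p-values. Against N2, and over both arrays of each strain, limma called 1116 features higher and 879 lower in NR350, 127 and 51 in VP303, and 104 and 64 in TU3401. In NR350 the largest rises were those of the sperm gene msp-78 (4.18, SE 0.17, uncertain because of its near-identical family), the collagen genes col-13 (3.86, SE 0.22) and col-81 (3.73, SE 0.16), sur-5 (3.84, SE 0.13) and Y59H11AM.1 (3.84, SE 0.16). Y54G2A.10 (-2.73, SE 0.49), M163.12 (-2.39, SE 0.38), pud-4 (-2.23, SE 0.15), sysm-1 (-2.13, SE 0.20) and M163.15 (-1.98, SE 0.38) were lowest. In VP303, rol-6, the noncoding B0495.11 (4.47, SE 0.12) and T01B7.11 (3.36, SE 0.16), col-81 (2.49, SE 0.16) and rde-1 rose most, and pud-4 (-1.78, SE 0.15), sysm-1 (-1.58, SE 0.20), drd-50 (-1.50, SE 0.18), sgnh-1 (-1.50, SE 0.24) and W03A3.4 (-1.28, SE 0.24) fell most. In TU3401, saeg-2 (2.05, SE 0.17), msp-78 (1.99, SE 0.17), col-81 (1.86, SE 0.16), ZK131.14 (1.84, SE 0.21) and sid-1 rose most, and pud-4 (-1.92, SE 0.15), F26H11.9 (-1.48, SE 0.27), asm-3 (-1.32, SE 0.24), dct-1 (-1.29, SE 0.17) and fbxb-40 (-1.18, SE 0.18) fell most. Mean intensities lay under 32 in N2 for rol-6, B0495.11, T01B7.11 and col-13, in NR350 for pud-4 and sysm-1, and in VP303 and TU3401 for pud-4, so the floor of the scale limits these differences and their ranks. All 3 strains were set against the same 2 N2 arrays, so genes that recur, such as pud-4 and col-81, are not independent observations. Without a variance trend, adjusted p lay above 0.05 for the 5 lowest named genes of VP303 and of TU3401, for Y54G2A.10, M163.12 and M163.15 in NR350, and for col-81 and ZK131.14 in TU3401. In total, the calls without a trend were 733 and 618 in NR350, 32 and 10 in VP303, and 21 and 18 in TU3401; the TU3401 split was 109 higher and 34 lower under quantile normalization and 90 and 85 with arrays centred on their medians.

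The last comparison by groups set the tissue markers of NR350 against those of N2. Of 22 muscle markers, 14 rose in NR350 over all genes and 0 fell, and 17 passed adjusted over the list alone; myo-3 (1.43, SE 0.13), unc-54 (1.52, SE 0.23) and unc-15 (1.32, SE 0.17) led them. Of 18 intestine markers, 11 rose and 1, cpr-6 (-0.56, SE 0.08), fell, with ifb-2 (1.41, SE 0.15) highest and 14 past the threshold adjusted over the list alone. Of 170 cuticle collagens, 59 rose and 5 fell over all genes, 75 passed adjusted over the list alone, and col-13 and col-81 were highest. Of 24 oocyte and eggshell genes, 3 fell, cey-3 (-0.58, SE 0.12), pos-1 (-0.50, SE 0.10) and oma-2 (-0.49, SE 0.10), and 5 passed adjusted over the list alone. These 4 lists passed camera with the preset correlation, with adjusted p from 1.08e-16 for collagens to 6.61e-05 for oocyte genes. None held with an estimated correlation: the adjusted p was 0.138 for collagens, muscle and intestine markers and 0.396 for oocyte genes. In fry, which asks whether the members of a list move one way and not whether they differ from other genes, the adjusted p was 0.00304 for collagens, 0.00278 for muscle markers, 0.00292 for intestine markers and 0.151 for oocyte genes. Neuron markers (median 0.05) and germ line genes (-0.08) did not pass camera (adjusted p of 0.0738 and 0.583), and in each list 1 gene rose, egl-21 and prg-1, and 1 fell, unc-18 and glp-1. Running the lists between strains and naming these genes were decided after the data were seen.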

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

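The limma class contrast and the test on short RNAs were fixed before their results were seen; the count of near-identical features and the use of the class contrast on the 41 features were chosen afterwards.

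The class contrast named 7 genes whose response went one way in both N2 and VP303 and the other way in both NR350 and TU3401. Lower in the arrays labelled ash-2 of N2 and VP303 and higher in the other strains were pix-1 (class difference -1.77) and C04E7.7 (-1.73), the latter resting largely on the TU3401 array labelled ash-2 (1.72 in TU3401, 0.20 in NR350). The reverse held for Y39B6A.1 (1.29), the insulin-like genes daf-28 (1.16) and ins-30 (1.09), col-94 (1.07) and nssp-64 (1.06). None passed the limma test of the difference over all features, with adjusted p of 0.0821 for pix-1, 0.208 for C04E7.7, 0.108 for Y39B6A.1, 0.43 for daf-28, 0.669 for ins-30, 0.324 for col-94 and 0.234 for nssp-64. These genes were picked for lying apart, so a common sign within each class is partly the selection. Groups of 1 array allow no search for outlying arrays within a group.

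A wider pattern of the same kind is the lower signal of mainly unnamed features in the arrays labelled ash-2 of N2 and VP303: over the 41 features, the median difference was -1.11 in N2, -1.47 in VP303, -0.19 in NR350 and 0.03 in TU3401, while the N2 and VP303 control arrays stood apart, with median log2 levels of 7.97 and 8.22 against 5.45 and 6.10 in the controls of the other strains, where less room was left to fall. With near-identical features counted once, the pattern still held 12 features, against at most 3 for any other pair of strains. Counting features so alike more than once is thus not its whole cause. Features that read 1 RNA at levels further apart than 0.05 were not merged, so repeated counting in that wider sense stays open. For lower recovery of short RNAs, the level set beforehand was a median under -0.5 for noncoding RNAs of 50 to 100 annotated bases. The median of 84 such features was -0.32 (interval -0.48 to -0.25), so that level was not reached, but a smaller loss would miss it. Longer RNAs differed less, by -0.10 for 115 features of up to 200 bases and -0.07 for 54 longer ones. From the shortest class to the longest, 8, 0 and 1 features were 2-fold lower. That order goes with a loss of short RNAs, so such a loss stays open. So does any loss among the 36 features without a symbol, which have no annotated length. A response to ash-2 RNAi reaching the intestine remains a possible explanation that cannot be told apart from differences between single arrays. Of the 41 features, 0 passed the limma test of the class contrast at an adjusted p under 0.05 (smallest 0.0821). When only features with 1 symbol were tested, 2 of the 4 with 1 symbol, pix-1 and F08G2.13, passed (0.0424). The test over all features recovered 1.6% of simulated 2-fold and 45.4% of simulated 4-fold changes, made in features with a mean log2 above 5.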

How the results depend on the processing

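Of the counts and correlations reported, 175 of 245 values under an alternative stayed within 1.5 times the main count or within the spread of correlations over pairs of strains, and no result past its threshold changed direction. The 175 include values that could not move, since correlations do not depend on the fold threshold. They also include the counts within strains in the upper 50% of mean level, which held every feature changed 2-fold. The share is thus no measure of robustness. Over all 28 lists, camera's direction turned in 11 of 168 comparisons, all 11 in lists that did not pass (8 lists, smallest adjusted p 0.192). Among these were the intracellular pathogen response under quantile normalization, desaturases with intensity minus 16, and DNA replication, neuron and oocyte lists without N2. The balance of higher and lower features did turn in places. The shared comparison went from 1041 and 1180 at an unadjusted p under 0.05 to 1344 and 849 with median centring. It also turned without a variance trend (1285 and 904) and in the upper 50% of mean level (816 and 670). Protein-coding genes (936 and 638) and features with 1 symbol (1031 and 967) gave the same turn. TU3401 went from 15 and 23 at 2-fold to 266 and 201 at 1.5-fold, and VP303 from 12 and 89 to 8 and 3 among protein-coding genes. Against N2, the TU3401 calls went from 104 and 64 to 36 and 47 among protein-coding genes. Where the construction does not show the cause, the cause was not tested. The control and ash-2-labelled arrays are paired by strain; without the strain block, 0 features were higher and 0 lower in the shared comparison in limma, as with it, with 333 and 557 at an unadjusted p under 0.05 against 1041 and 1180.

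For the shared comparison, features with 1 symbol gave 1 higher and 1 lower, protein-coding genes gave 1 higher, and leaving out 1 strain gave 0 to 1 higher and 0 to 24 lower, the highest without TU3401. For the class contrast, an adjusted p under 0.10 gave 3 higher, all without a symbol, and 24 lower, features with 1 symbol gave 3 lower, and leaving out 1 strain gave 6 to 20 higher and 0 to 42 lower. Between strains, eBayes without a trend gave 32 higher and 10 lower in VP303, 733 higher in NR350, and 21 and 18 in TU3401. An adjusted p under 0.10 gave 204 and 79 in VP303, 1415 lower in NR350, and 188 and 158 in TU3401. In TU3401, protein-coding genes gave 36 higher and 47 lower, and quantile normalization gave 34 lower.

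Within strains, a 1.5-fold threshold gave 130 higher and 284 lower in N2, 143 and 181 in VP303, 85 and 216 in NR350 and 266 and 201 in TU3401. Intensity minus 16, chosen after seeing the data, gave 58 and 169, 91 and 160, 50 and 157, and 135 and 199 in the same order; whether a smaller offset or noise in dim features raised the counts was not tested. Near-identical features counted once gave 39 lower in N2 and 29 in VP303. Protein-coding genes alone gave 10 higher and 10 lower in N2, 8 higher and 3 lower in VP303, 6 higher and 8 lower in NR350, and 9 higher and 11 lower in TU3401.

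At 1.5-fold, N2 and VP303 shared 13 higher and 104 lower features and the other pairs at most 17 and 60. With intensity minus 16, they shared 4 higher and the other pairs at most 9 higher and 26 lower, with a Pearson correlation of 0.186 for N2 and VP303 and at most 0.131 for the others. Near-identical features counted once gave 19 shared lower in N2 and VP303, whose Pearson correlation of 0.212 was then below N2 and NR350 (0.243) and NR350 and TU3401 (0.234). Protein-coding genes gave 3 shared lower, and the other pairs shared at most 2 higher and 3 lower. Their Pearson correlation was 0.0902 for N2 and VP303 and up to 0.26 for the others, so there too N2 and VP303 were not the pair with the highest value.

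Where 11 lists were higher in camera, 0 were with an estimated correlation, 0 with fry, 5 under quantile normalization, and 7 to 12 when 1 strain was left out, the lowest without N2. The lists were not always among the 11: without NR350 they included cuticle collagens (adjusted p 0.0405) and the H3K4 machinery (0.0445) and lacked SKN-1 genes, without VP303 the H3K4 machinery and oocyte genes, and without TU3401 collagens, heat shock genes and neuron markers. With the upper 50% of features, 7 list medians lay below the random range in place of 3. Among named genes, 625 of 631 values of the shared comparison, 218 of 248 of the class contrast and 382 of 403 of the strain differences kept their side of the threshold. Direction was compared only where the main or the alternative fit passed, and no such value changed direction. Changes of sign among values that passed in neither fit were not counted. Of the strain calls, 20 were lost, most of them without a variance trend. F26H11.9 and asm-3 in TU3401 were also lost under quantile normalization. Y54G2A.10 and M163.15 in NR350 and F26H11.9 in TU3401 were also lost with a robust prior. The low signal of most features, 31.3% having a mean intensity above 32, limits what dim genes can show.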

Other observations

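The limma comparisons, the quantile normalization and the fit without a strain block were fixed beforehand; the lists tested between strains, the tests of explanations and the counts of splits were chosen after the results were seen.

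The gene lists also differed between the other strains and N2 in ways not described above. In VP303, cuticle collagens (median 0.04) had 11 members past the limma test over all genes, 10 of them higher. Ribosomal proteins (median 0.17), respiratory chain subunits (0.18), intestine markers (0.22) and fatty acid desaturases and elongases (0.14) had higher medians than in N2, with 1, 1, 0 and 0 members past that test, and oocyte and eggshell genes (-0.17), DNA replication genes (-0.13) and vitellogenins (-0.23) lower ones, with 1, 0 and 0. In TU3401, innate immunity effectors (0.23), ribosomal proteins (0.19) and respiratory chain subunits (0.12) had higher medians, with 2, 2 and 0 members past the test, and moulting genes (-0.22), the RNAi machinery (-0.16), the endoplasmic reticulum unfolded protein response (-0.13) and neuron markers (-0.09) lower ones, with 0 members past it. Under quantile normalization the TU3401 medians were -0.14 for moulting genes, -0.06 for the RNAi machinery, -0.05 for the endoplasmic reticulum unfolded protein response and 0.20 for respiratory chain subunits. All of these passed camera with the preset correlation at an adjusted p of at most 0.00747. None held with an estimated correlation, where the adjusted p was at least 0.344 in VP303 and 0.517 in TU3401, nor with fry (smallest adjusted p for these lists 0.0671 and 0.118). For the class contrast, collagens (median 0.03) and neuron markers (0.15) passed with the preset correlation, and the adjusted p was 0.878 with an estimated one.

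Some innate immunity effectors differed between NR350 and N2. In NR350, dod-19 (2.09, SE 0.19), clec-67 (1.82, SE 0.16) and lys-1 (1.33, SE 0.14) were higher than in N2 and sysm-1 was lower (-2.13, SE 0.20, limited by the floor since its NR350 intensity lay under 32), each past the limma threshold (adjusted p of 7.35e-05, 5.53e-05, 2.49e-04 and 9.51e-05). Of 28 innate immunity effectors, 9 passed in NR350 over all genes, 8 of them higher, and 13 passed adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 0.00147) but not with an estimated correlation (adjusted p = 0.357), and fry gave an adjusted p of 0.0472.

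The ash-2 signal was higher in the arrays labelled ash-2 in 4 of 4 strains. A single exchanged pair of arrays is argued against by that number, 4, since an exchange in 1 strain leaves the other 3 lower. Among the explanations that stay open are RNA of the feeding trigger read by the ash-2 feature and labels exchanged in all 4 strains; others were not tested. The difference in N2, where per the labels the RNAi acts in the whole body, lay 0.45 below the mean of the other 3 strains on the log2 scale (a value of -0.45). If the RNAi lowered the transcript most in N2, which was not measured, that value goes with the first and against the second. The value rests on 1 pair of arrays, and N2 would rank lowest of 4 by chance in 25% of cases, so these explanations cannot be told apart here.

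NR350 stood apart from the other strains, with 1995 features called against N2. A remaining difference in scale between the deposited arrays is argued against, because 1927 calls were made after quantile normalization. RMA already equalises arrays by quantiles, so this step repeats part of the processing and is not an independent check. A lower share of germ line would raise all somatic tissues alike. Muscle markers exceeded neuron markers by 0.49 in the difference from N2 (interval 0.01 to 0.97, 20 and 12 members above an intensity of 32). This does not decide the matter, because the interval nearly reaches 0 and treats genes as independent, and the floor compresses dim genes. Slightly younger animals on the NR350 arrays are a candidate explanation: of 4 lists, all 4 had the sign this would give, collagens (0.14) and sperm genes (0.11) higher and oocyte genes (-0.23) and vitellogenins (-0.33) lower, with intervals that treat genes as independent; in camera with an estimated correlation none of the 4 held (adjusted p of 0.138, 0.166, 0.396 and 0.406 in that order), while fry gave 0.00304, 0.00278, 0.151 and 0.146. Only 3 of 16 sperm genes and 59 of 170 collagens had a mean log2 above 5, so most members of these lists were dim. Against the same 2 N2 arrays, the medians had the same 4 signs and smaller sizes in the other strains. In that order they were 0.04, 0.02, -0.17 and -0.23 in VP303 and 0.03, 0.03, -0.08 and -0.19 in TU3401. The signs are thus not particular to NR350, and a difference of the N2 arrays would give them too. Lower oocyte genes would also go with a lower share of germ line. The 28 germ line genes themselves had a median of -0.08, and 1 passed the limma test as higher and 1 as lower. That list passed neither camera with the preset correlation (adjusted p = 0.583) nor fry (adjusted p = 0.595), so it gave no clear sign of such a share. Differences that the strain itself brings, including its transgene, were not tested and stay open.

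For the first comparison, 2221 features had an unadjusted p under 0.05 in limma. Exchanging the arrays within strains makes 8 splits that part every pair; the real one gave the most (1 of 8), the highest of the others gave 1510, and 8 splits are too few for a share under 0.05. Without the strain block, 24 of the 35 splits of the 8 arrays gave at least the 890 features of the real one, so chance cannot be excluded there; the highest, 3210, set N2 and VP303 against NR350 and TU3401, which is a structure of strains.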
